A study of Mus musculus with 14 samples.

How the data were processed

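Small RNA was measured by sequencing in 14 mouse testis libraries of 6 groups. Per the labels' protocols, total small RNA of 16 to 40 nt was isolated from a gel at embryonic day 16.5, and RNA bound to MILI or MIWI2 was recovered from immunoprecipitates at postnatal day 0. Libraries were made with the NEBNext multiplex small RNA kit and sequenced on a HiSeq 2000. The heterozygous and mutant groups hold 3 libraries each for total RNA and 2 each per antibody. Groups were taken from the labels. The labels give no replicate numbers, so libraries are numbered within a group in the order listed, and this order was not used to pair libraries.

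The deposited file gives whole-number counts of reads for 28383870 distinct mapped sequences in each library, not normalized, with the sequence's length, its number of genomic alignments, the position of one alignment, and an annotation. The reads were mapped to mm10 (GRCm38), per the submitters' processing notes. The aligner, its settings and the adapter trimming are not given in the sources used here. Every sequence was checked: its listed length, its flags for the base 1 and base 10 and its total over libraries matched the sequence and counts in all 28383870 cases. Positions were checked on 51 sequences against single-exon transcripts, and in all 51 the listed start was the 1-based 5' end. Reads mapped to a locus in several copies are listed at one alignment only, and this decides the family or gene they count for. The reference was GENCODE annotation of GRCm38 with gene, exon and microRNA positions. The authors' annotation was used in the order they give it, microRNA before other small RNAs and repeats, then genes, then none.

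Depth ran from 5106928 to 11972688 reads per library. Of piRNA-sized reads, 38.7%, 42.9% and 43.5% were uniquely placed in heterozygous and 34.1%, 33.7% and 33.6% in mutant total libraries. The shares were 80.9% and 77.1% against 53.6% and 56.2% with MILI, and 44.9% and 43.1% against 30.1% and 30.3% with MIWI2. Gene counts of replicate libraries differed by more than sampling noise in every pair of a group (chi-square per degree of freedom from 1.37 to 4.70), and no library was counted as a repeat of another. Shares of single libraries carry Wilson 95.0% intervals, and a count of 0 was set to a floor of 3 counts over a group before a fold was taken. Neither covers anything but counting error.

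The piRNA window was 24 to 32 nt. For each library the share of reads in it, the shares with uridine at base 1 and adenine at base 10, the share of each annotation class, and the share of antisense reads among L1 and IAP reads were computed with every read counted once. The ping-pong measure was the z-score of the 10-nt overlap of 5' ends on opposite strands against the other overlaps of 1 to 20 nt, over uniquely placed reads. Groups were compared on each value with an exact two-sided permutation test of the difference in means, adjusted by Benjamini-Hochberg over the classes of a library type. The smallest p is 0.1 for 3 against 3 libraries and 0.333 for 2 against 2.

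RPM are reads scaled to all mapped reads of the library. Counts were summed over 4 kinds of feature. microRNAs were reads of 18 to 26 nt in precursors, and those listed as antisense to a precursor were given to the microRNA annotated on the other strand at that place, 3.12% to 4.11% of microRNA reads in total libraries. Genes were uniquely placed piRNA-sized reads in sense with exons. Element families were piRNA-sized reads by the family listed, sense and antisense separately. Windows were uniquely placed piRNA-sized reads of both strands in bins of 10 kb. Each was tested with edgeR's quasi-likelihood test after filterByExpr and TMM scaling, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. The 6 total libraries were fitted together, and the 8 precipitates in 1 fit of 4 groups that share their spread, with a contrast per antibody, their interaction, and MIWI2 against MILI within each genotype. Both fits leave 4 residual degrees of freedom. After filtering, 396 of 877 microRNAs, 2520 of 17478 genes, 1362 of 2076 family features and 17960 of 191783 windows were tested in total RNA, and 5273 of 19719 genes, 1852 of 2135 family features and 59470 of 228250 windows in the precipitates. TMM assumes that most features do not move. Element families move widely here, and their TMM factors in the precipitates ran from 0.389 to 2.55, so every log2 value is relative to the bulk of the features in its fit.

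Lists of features fixed before the data were examined were tested with fry in the same fits. fry's directional p asks whether members move on balance one way, and it does not compare them with other features; camera with an estimated correlation, which does, was run as an alternative. The gene lists were piRNA pathway, germ cell, Sertoli, Leydig, interstitial and peritubular, blood, endothelial, histones and ribosomal proteins, the last by symbol, so that it holds Rps6k kinases. The microRNA lists were germ cell and pluripotency, the Mir17 to Mir92 cluster, let-7, somatic gonad and mesenchyme, blood, endothelial, muscle, neural, Dlk1-Dio3 imprinted, and Mir34b with Mir449. The element lists were young L1, older L1, IAP, other ERVK, ERV1, MERVL, MaLR and SINE, on each strand. Members without reads in the file, such as Hba-a1, are not in the tested counts. The tests, lists, window, thresholds and most alternatives were chosen before the data were examined.

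The features named follow a rule fixed at the same time. It takes, among called features whose libraries of one group all lie above those of the other, up to 12 higher and 12 lower by adjusted p, leaving out predicted genes; the 10 most abundant; up to 4 members of each list, the most abundant; and for windows the 5 most abundant and up to 5 called in each direction. For the interaction no separation of groups was asked. Not every feature the rule allows is named, and a few are not reported here. Outside the rule, 4930539E08Rik, Morc1, Exd1, Gtsf1 and Rps2 were named after their values were seen, to give the members behind small counts. Positions come from the annotation.

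The fits were tested on simulated data drawn from the real means and library sizes, with 200 features changed and 50 at each fold of 1.5, 2, 4 and 8. In total RNA edgeR recovered 58%, 86%, 98% and 94% of changed microRNAs at these folds, 8%, 44%, 82% and 80% of genes, 54%, 84%, 90% and 94% of family features and 0%, 10%, 76% and 90% of windows. For MILI it recovered 6%, 42%, 88% and 88% of genes, 62%, 86%, 96% and 96% of family features and 0%, 10%, 74% and 82% of windows. For MIWI2 these were 0%, 2%, 18% and 46% of genes, 50%, 68%, 92% and 94% of family features and 0%, 4%, 46% and 54% of windows. For the interaction they were 0%, 0%, 22% and 50% of genes, 20%, 58%, 78% and 84% of family features and 0%, 0%, 20% and 34% of windows. For MIWI2 against MILI they were 0%, 22%, 62% and 88% of genes and 64%, 82%, 94% and 96% of family features in heterozygotes, and 0%, 2%, 52% and 62% of genes and 38%, 76%, 80% and 94% of family features in mutants. False calls numbered 2 to 24 per comparison. With MILI and MIWI2 over 200 of each kind were called, so false calls at that scale were not tested. A raised list of 12 passed fry in each comparison but MIWI2 genes, and at most 2 of 20 unchanged lists had a p under 0.05.

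Alternatives chosen before the data were examined were RLE size factors, library totals without TMM, DESeq2, no filter on low counts, leaving out each library, reads of 26 to 30 nt, distinct sequences counted once, uniquely placed reads for families and class shares, a separate fit per antibody, scaling to microRNA precursor reads in total RNA, windows of 50 kb, and camera. Added after seeing the data were microRNA names as in the file, all reads without the 28 nt chromosome 9 sequence, uniquely placed reads for the element and IAP shares, reads with any number of alignments for genes and windows, library totals for the lists, the permutation over total and precipitate libraries together, and reads per 100 microRNA reads. The shares of all elements, of IAP reads and of L1 and IAP reads by strand among piRNA-sized reads, and adenine at base 10 by element, were also added then. Weighting each alignment by 1 over its number was not run, since one alignment is listed per sequence. Structural RNA classes in the precipitates, each a small part of the reads, are not reported. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.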

Results

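Small RNA was sequenced from mouse testes heterozygous (Tex15+/-) or homozygous mutant (Tex15-/-) for Tex15, a germ cell gene needed for male meiosis and for the silencing of transposable elements. The study asked what loss of TEX15 does to the small RNAs of the fetal testis and to the piRNAs held by MILI (PIWIL2) and MIWI2 (PIWIL4), the PIWI proteins of perinatal male germ cells. Total small RNA of 16 to 40 nt came from 3 heterozygous and 3 mutant samples of embryos at E16.5. RNA precipitated with MILI or with MIWI2 came from postnatal day 0, with 2 samples per genotype and antibody, so that the 14 libraries formed 6 groups. Heterozygous total libraries held 8110985, 11972688 and 9881053 mapped reads, and mutant ones 9289456, 8793250 and 7964593. MILI libraries held 8629155 and 8009593 reads in heterozygotes and 7311348 and 5767645 in mutants, and MIWI2 libraries held 7528383 and 6549932 in heterozygotes and 5848973 and 5106928 in mutants. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Reads carry no molecular identifiers, and intervals and floors therefore cover counting error only. Reads of 24 to 32 nt are called piRNA-sized below, and RPM are reads scaled to the mapped reads of the library. Log2 differences are mutant over heterozygote, with standard errors and Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test. Positions are on mm10. Permutation tests were exact and two-sided; 3 against 3 libraries cannot give a p under 0.1, and 2 against 2 cannot give one under 0.333.

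Tex15 itself (chromosome 8, 33516689 to 33592503) was counted first, as reads in sense with its exons. The heterozygous total libraries held 19, 31 and 26 such reads and the mutant ones 2, 3 and 2, that is 2.52 ± 0.156 and 0.269 ± 0.0649 RPM (SD, n = 3 each), 9.44-fold apart. MILI precipitates held 38 and 36 reads in heterozygotes, 4.45 ± 0.0643 RPM (SD, n = 2), and 0 and 0 in mutants, which makes the heterozygous level at least 19.4-fold higher against a floor of 3 counts over the mutant group. MIWI2 precipitates held 3 and 2 reads in heterozygotes and 0 and 0 in mutants. Each library labelled mutant thus had a lower Tex15 RPM than each library labelled heterozygous of the same kind.

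**Figure D1:**
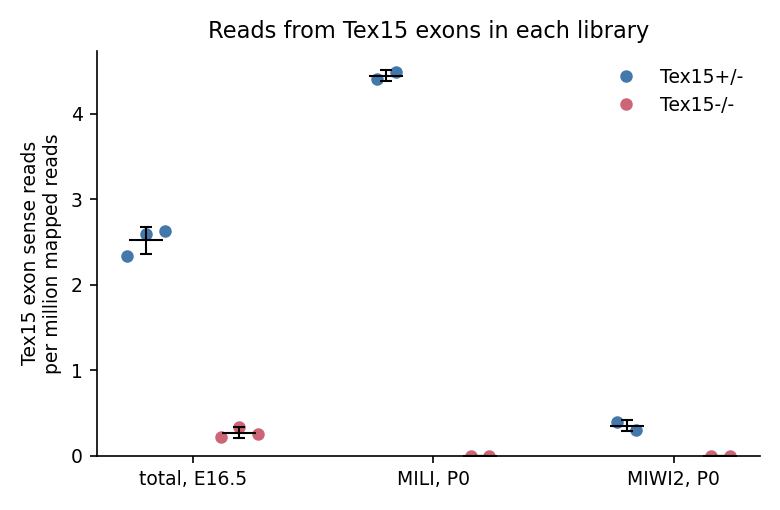
RPM in sense with Tex15 exons, one point per library, for total small RNA at E16.5 and for MILI and MIWI2 precipitates at postnatal day 0. Heterozygous total libraries lie around 2.52 RPM and mutant ones around 0.269, and the mutant precipitates hold 0 reads.

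The first comparison asked how the small RNAs of the fetal testis as a whole differed between genotypes at E16.5. Among piRNA-sized reads, those from IAP elements, the most active endogenous retroviruses of the mouse, took a larger share in every mutant library, and those from SINEs, exons, introns and sequence outside genes and repeats took smaller shares. IAP reads made up 11.2% ± 0.618 of piRNA-sized reads in heterozygotes and 18.03% ± 0.457 in mutants (SD, n = 3 each; exact p = 0.1). SINE reads stood at 5.62% ± 1.17 and 2.95% ± 0.199, and intron reads at 5.65% ± 0.741 and 3.77% ± 0.0316. Exon reads stood at 5.44% ± 0.880 and 4.19% ± 0.307, and reads outside genes and repeats at 10.6% ± 2.15 and 6.76% ± 0.292. Within the total libraries each of these classes separated the genotypes at the smallest possible exact p of 0.1 (adjusted 0.171). An exact permutation over total libraries and the precipitates of one antibody together was chosen after the data were seen. It averages both and does not test total RNA alone. That permutation gave an exact p = 0.0167, the smallest that 120 arrangements allow, and an adjusted p of 0.0333 over 24 tests for SINE, exon, intron and unannotated reads with either antibody. LTR elements as a class took 28.4% ± 4.20 and 34.5% ± 1.95 (exact p = 0.2), LINEs 27.3% ± 2.72 and 27.2% ± 3.02 (exact p = 1), and all elements together 61.7% ± 7.50 and 64.9% ± 4.49 (exact p = 0.5). The LINE difference took either sign when 1 library was left out, from -1.66 points without mutant library 1 to 1.498 without heterozygous library 2.

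Antisense reads made up 51.6% ± 2.50 of IAP reads in heterozygous and 52.6% ± 3.24 in mutant total libraries (exact p = 0.8), a difference that ran from -0.174 points without mutant library 2 to 2.83 without mutant library 3. Antisense IAP reads with adenine at base 10, the mark of piRNAs made by the ping-pong cycle of reciprocal cleavage, took 45.5% ± 1.38 in heterozygotes and 56.0% ± 1.14 in mutants, higher in 3 of 3 mutant libraries (exact p = 0.1). Antisense reads made up 58.6% ± 0.830 of L1 reads in heterozygotes and 55.8% ± 1.84 in mutants (exact p = 0.1). Over all piRNA-sized reads, uridine at base 1, typical of primary piRNAs, stood at 72.7% ± 5.47 and 69.7% ± 1.95 (exact p = 0.5), and adenine at base 10 at 32.3% ± 3.15 and 35.0% ± 1.67 (exact p = 0.3). The z-score of the 10-nt overlap between opposite strands was 6.99 ± 2.72 and 2.69 ± 2.12 (exact p = 0.2). piRNA-sized reads were 46.3% ± 8.92 of all reads in heterozygotes and 40.4% ± 2.99 in mutants (exact p = 0.4).

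**Figure D2:**
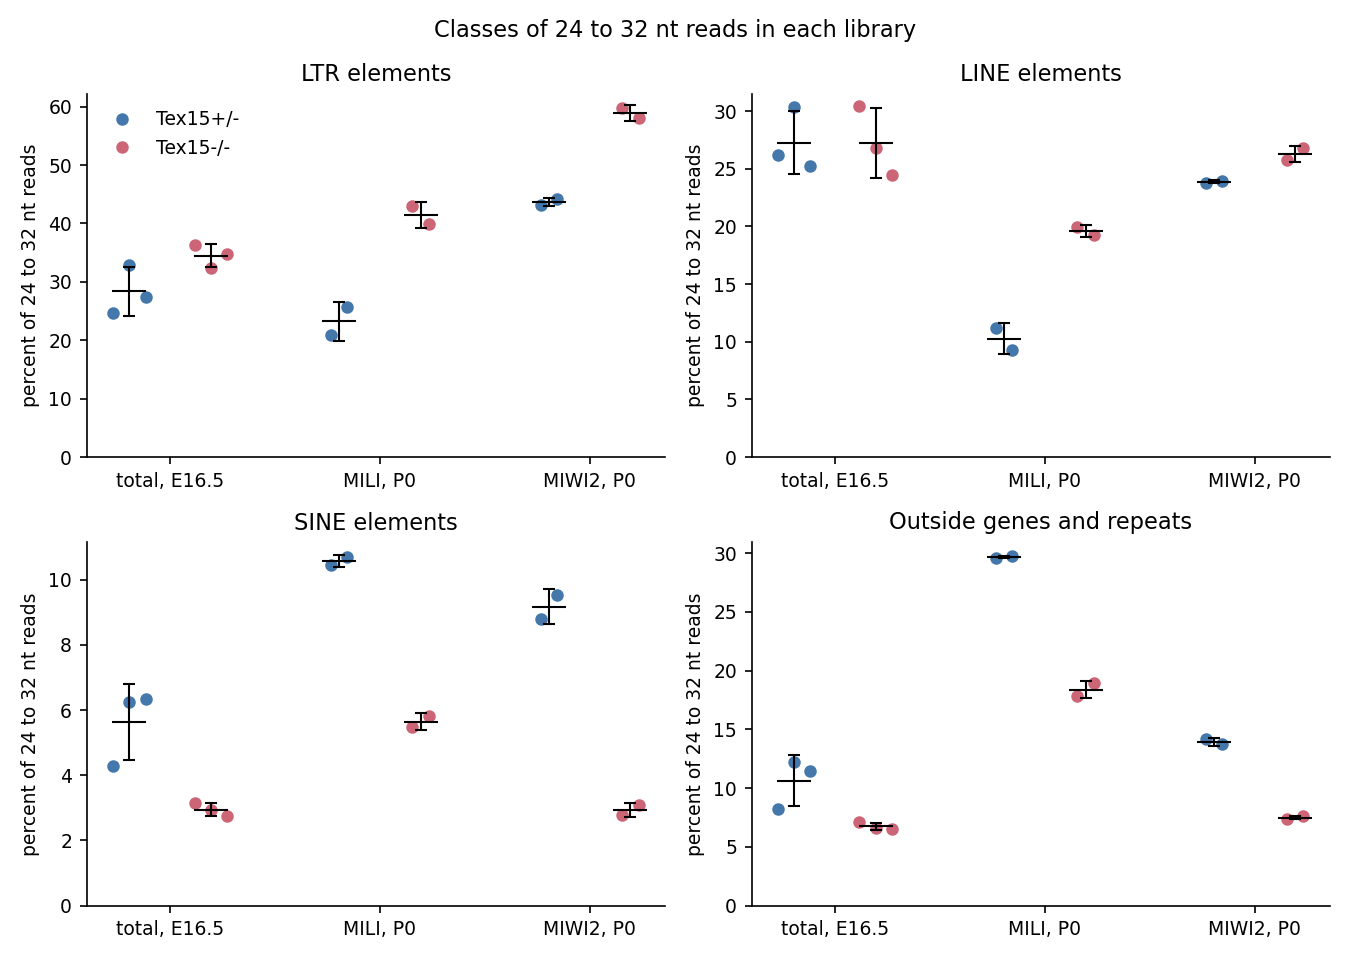
Percent of piRNA-sized reads (24 to 32 nt) from LTR elements, LINEs, SINEs and sequence outside genes and repeats, one point per library with group means and SD. SINE reads lie lower in every mutant library of all 3 kinds (2.95% against 5.62% in total RNA, 5.65% against 10.6% with MILI, 2.95% against 9.17% with MIWI2), and LTR reads higher in every mutant precipitate.

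Of all mapped reads in the total libraries, microRNA precursors gave 41.0% ± 8.86 in heterozygotes and 43.1% ± 0.492 in mutants (exact p = 0.7), a difference between -2.74 points without heterozygous library 2 and 6.02 without heterozygous library 1. Ribosomal RNA gave 3.16% ± 1.74 and 9.50% ± 2.71 (exact p = 0.1, adjusted 0.2), higher in 3 of 3 mutant libraries, and transfer RNA 6.25% ± 3.47 and 4.03% ± 1.80 (exact p = 0.4). Among 396 microRNAs tested, 3 were higher in mutants and 0 lower. In simulated data with 200 microRNAs changed, this fit called 6 unchanged ones by mistake. With so many changed, this does not give the real share of false calls. The 3 called here were mir-6236 (chromosome 9, 110281287 to 110281409), from 146 ± 58.8 to 877 ± 338 RPM (SD, n = 3; log2 2.54 ± 0.30, adjusted p = 0.0091), mir-6538 (chromosome 12, 26414901 to 26415010; log2 2.66 ± 0.41, adjusted p = 0.033) and mir-6240 (chromosome 5, 114851948 to 114852064; log2 2.08 ± 0.36, adjusted p = 0.049). Ribosomal RNA reads, higher in the same libraries, share sequence with mir-6236 and mir-6240, so these names are uncertain. The 10 most abundant microRNAs, among them mir-148a, mir-10b, mir-143, let-7g and let-7i, differed by log2 -0.23 to 0.09 (adjusted p = 0.97 or above). DESeq2 also called 3 microRNAs, and 15 had an unadjusted p under 0.05. The count was 9 without heterozygous library 1 and 1 without heterozygous library 2, heterozygous library 3 or mutant library 3. mir-6538 lost its call without heterozygous library 2 (adjusted p = 0.066), heterozygous library 3 (0.051) or mutant library 3 (0.11), and mir-6240 without heterozygous library 2 (0.066), heterozygous library 3 (0.29) or mutant library 1 (0.11), 2 (0.13) or 3 (0.16).

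No member of any microRNA list fixed in advance was called over all microRNAs. The imprinted Dlk1-Dio3 cluster moved up on balance by the fry test (31 of 32 members tested, median log2 0.03, adjusted p = 0.00261; adjusted p = 0.683 with an estimated correlation). Muscle microRNAs had 3 of 5 members tested, none called over all microRNAs and 3 lower when adjusted over the list alone, with mir-206 at log2 -1.11, mir-133a-1 at -0.55 and mir-1a-2 at -0.49 (fry adjusted p = 0.292; 0.514 with an estimated correlation). The germ cell and pluripotency list (7 members tested, median -0.21), let-7 (12, median 0.04), blood (6, median 0.21), neural (2, median -0.29) and somatic gonad microRNAs (9, median -0.05) each had a fry adjusted p of 0.758. The last of these changed direction when scaled by library totals. The Mir17 to Mir92 cluster (12, median 0.04, mean -0.00, tested upwards) gave 0.937 and Mir34b with Mir449 (3, median -0.10) 0.836, the latter also turning with library totals. Endothelial microRNAs had fewer than 2 members tested. With each list taken alone, no microRNA of these other lists was called either.

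Element families, counted separately for sense and antisense reads, gave 116 calls of 1362 in total small RNA, 101 higher and 15 lower in mutants. IAPEz-int, the coding body of IAP elements, rose from 10314 ± 2053 to 24027 ± 3082 RPM in antisense (log2 1.99 ± 0.22, adjusted p = 5.1e-05, higher in 3 of 3 mutant libraries) and from 17169 ± 2002 to 26282 ± 3016 sense reads (log2 1.36, adjusted p = 0.0027). IAPLTR1a_Mm antisense reads (log2 1.47, adjusted p = 9.4e-06) and IAPEy-int sense reads (log2 1.44) rose with it. Other ERVK families, retroviruses of the same class, rose too, with ETnERV-int antisense at log2 1.46 (adjusted p = 4e-05), MMERVK10C-int antisense at 1.21 and ERVB4_1C-LTR_Mm sense at 1.27. L1Md_F3 sense reads rose by log2 1.34 and MERVL-int antisense reads by 0.85, and L1Md_T sense reads, from the youngest L1 elements, by 0.91 (adjusted p = 0.0099). L1Md_T and MERVL-int turned to log2 -0.08 and -0.20 when scaled to microRNA reads. B1_Mus1 antisense reads, from a young SINE family, fell by 0.60 on the log2 scale (2086 ± 659 to 788 ± 156 RPM, adjusted p = 0.016). The L1Md_T call ended without heterozygous library 3 (adjusted p = 0.06) or mutant library 1 (0.11), and that of B1_Mus1 without heterozygous library 3 (0.053) or mutant library 1 (0.071), 2 (0.077) or 3 (0.13).

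By list, 9 of 11 IAP families were higher in sense and 7 of 11 in antisense, and 11 and 10 when adjusted over the list alone, with median log2 0.73 and 0.66 (fry adjusted p = 0.00345 and 0.00283; adjusted p = 0.109 and 0.0886 with an estimated correlation). Other ERVK families had 7 and 6 of 9 higher (8 and 8 over the list alone), with fry adjusted p = 0.00757 and 0.00778 (both 0.109 with an estimated correlation). Young L1 had 2 of 3 higher in sense and in antisense (2 and 3 when adjusted over the list alone; fry adjusted p = 0.00932 and 0.033, with an estimated correlation 0.109 and 0.245). Older L1 had 10 and 2 of 15 (12 and 9 over the list alone; 0.00932 and 0.0587, the first 0.245 with an estimated correlation). MERVL had 1 and 1 of 2 (2 and 2 over the list alone; 0.033 and 0.00932, with an estimated correlation 0.299 and 0.245). SINEs had 5 of 12 antisense families lower (7 over the list alone, median -0.38, fry adjusted p = 0.0283; 0.314 with an estimated correlation) and 0 of 12 sense ones (median -0.30, 0.0708). MaLR, older retrotransposons, had 0 of 6 called in either strand (1 sense family higher over the list alone; antisense median -0.17, fry adjusted p = 0.0283, 0.402 with an estimated correlation; sense median -0.14, 0.595). ERV1 sense, with 1 of 6 higher, had a median of -0.06 but a mean of 0.10 (fry adjusted p = 0.709), and ERV1 antisense 0 of 6 and a median of 0.14 (0.595).

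These directions rest on the scaling. The median family stood at log2 -0.89 when scaled by library totals and at -1.09 when scaled to microRNA reads. By edgeR the calls were then 1 (IAPEz-int antisense, log2 1.22, adjusted p = 0.045) and 0. The latter scaling had 260 families at an unadjusted p under 0.05, against 307 with the usual scaling, and 158 calls by DESeq2. The medians of the IAP lists then became -0.12 (sense) and -0.17 (antisense) with library totals, those of young L1 -0.07 and -0.09, and those of other ERVK families -0.12 and -0.25. IAP reads per 100 microRNA reads were 14.04 ± 6.42 and 17.6 ± 1.53 (SD, n = 3; exact p = 0.5), and SINE reads per 100 microRNA reads 7.26 ± 4.06 and 2.88 ± 0.384, lower in 3 of 3 mutant libraries (exact p = 0.1, adjusted 0.35). The count of families was 63 without mutant library 3 and 69 without mutant library 1, and at most 157, without heterozygous library 2.

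Genes, counted from uniquely placed piRNA-sized reads in sense with exons, gave 0 calls of 2520 in total small RNA by edgeR, with 214 at an unadjusted p under 0.05 and 1 call by DESeq2. Scaled by library totals the median gene stood at log2 -0.62, with 360 calls, 2 higher and 358 lower. Scaled to microRNA reads it stood at -0.74, with 16 calls, 2 higher and 14 lower. Without heterozygous library 1 the count was 112, and 1 without mutant library 1. Rn45s, the ribosomal RNA precursor, went from 55.4 ± 23.4 to 136 ± 17.4 RPM (log2 1.80 ± 0.35, adjusted p = 0.20; log2 2.42 without heterozygous library 1, adjusted p = 1.5e-14). Col1a1, Col1a2 and Col3a1, interstitial and peritubular collagens, stood at log2 1.40, 1.20 and 1.01 (adjusted p = 0.36, 0.48 and 0.47). They passed without heterozygous library 1, the highest heterozygote for each (log2 1.86, 1.98 and 1.57, adjusted p = 5.2e-06, 5.6e-05 and 0.0004). The interstitial list (4 of 8 tested, median 1.10, Pdgfra 0.01) had 0 called and 3 higher when adjusted over the list alone (fry adjusted p = 0.231). piRNA pathway genes (7 of 21 tested, median 0.18, fry adjusted p = 0.166), histones (11 of 72, 0.37, 0.231) and ribosomal proteins (19 of 103, 0.15, 0.166) had 0 called, and germ cell genes (4 of 16, median 0.00, mean -0.13, 0.443) 0 called and 1 lower when adjusted over the list alone. The piRNA pathway, histone and ribosomal protein medians turned negative with library totals. Sertoli, Leydig, blood and endothelial genes had fewer than 2 members tested.

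Windows of 10 kb gave 1503 calls of 17960 in total small RNA, 1442 higher and 61 lower. With library totals 442 were higher and 2272 lower, and the median window stood at log2 -0.82. The window at chromosome 9, 10190001 to 10200000, in the neural adhesion gene Cntn5, rose from 0.522 to 6.05 RPM (log2 4.29 ± 0.35, adjusted p = 0.00015), and those starting at 115970001 on chromosome 13 and 43330001 on chromosome 15 by log2 3.63 and 3.72. The window from 34660001 on chromosome 8 fell from 2.46 to 0.0359 RPM (log2 -4.94, adjusted p = 0.0016), that from 103230001 on chromosome 3 from 55.7 to 5.01 (log2 -2.70), and that from 21840001 on chromosome 6, at Tspan12, by 2.37 on the log2 scale. The chromosome 8 window, from 34660001, lies close to Tex15, which ends at 33592503. An effect of sequence linked to the mutant allele was not tested in total RNA. The 5 most abundant windows were microRNA loci and none was called. The count was 970 without mutant library 1.

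The second comparison asked how the piRNAs bound by MILI at birth differed between genotypes. In mutant MILI libraries IAP and sense L1 reads took larger shares, and SINE, gene and unannotated reads smaller ones. Elements gave 45.04% ± 2.27 of piRNA-sized reads in heterozygotes and 67.3% ± 2.51 in mutants (SD, n = 2 each; exact p = 0.333 here and for each MILI share below unless given). LTR reads stood at 23.3% ± 3.36 and 41.4% ± 2.24, LINE reads at 10.3% ± 1.35 and 19.6% ± 0.530, and IAP reads at 3.55% ± 0.614 and 10.5% ± 0.471. SINE reads stood at 10.6% ± 0.186 and 5.65% ± 0.253, exon reads at 10.7% ± 1.62 and 6.24% ± 1.01, intron reads at 13.4% ± 0.726 and 7.05% ± 0.709, and reads outside genes and repeats at 29.7% ± 0.117 and 18.4% ± 0.746. Each was lower in both mutant libraries. The combined permutation given above averages MILI with total RNA and does not test MILI alone. Antisense reads made up 71.3% ± 1.74 of IAP reads in heterozygotes and 50.9% ± 2.50 in mutants. Sense L1 reads took 4.30% ± 0.896 of piRNA-sized reads in heterozygotes and 12.98% ± 0.0138 in mutants. The antisense share of L1 reads, 55.2% ± 15.2 and 32.9% ± 1.84, is inflated in heterozygous library 1 by a single 28 nt sequence from chromosome 9 (66.0%, Wilson 95% interval 65.9 to 66.1, and 52.0%, 51.9 to 52.1, without it; 44.5% in library 2).

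Uridine at base 1 stood at 84.6% ± 1.27 of MILI reads in heterozygotes and 82.6% ± 0.292 in mutants (exact p = 0.333), and adenine at base 10 at 28.1% ± 2.81 and 30.9% ± 0.537. The 10-nt overlap z-score was 10.7 ± 0.507 and 10.9 ± 0.419, a difference from -0.240 without heterozygous library 1 to 0.478 without heterozygous library 2. piRNA-sized reads were 91.3% ± 0.423 and 90.7% ± 0.741 of all MILI reads (exact p = 0.667).

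**Figure D3:**
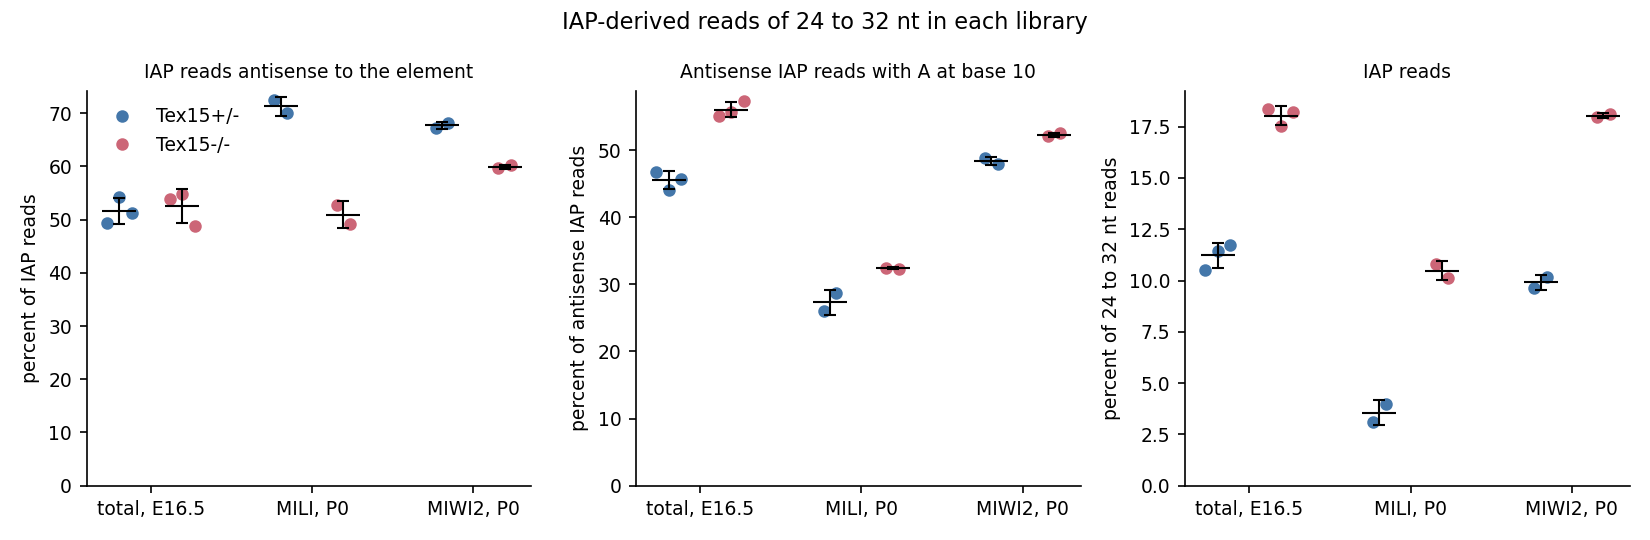
Antisense share of IAP reads, share of antisense IAP reads with adenine at base 10, and IAP share of piRNA-sized reads, in percent, one point per library with group means. The IAP share is higher in every mutant library (18.03% against 11.2% in total RNA, 10.5% against 3.55% with MILI, 18.04% against 9.91% with MIWI2), and the antisense share is lower in the mutant MILI libraries (50.9% against 71.3%).

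Of 1852 family features, 922 were called in MILI, 529 higher and 393 lower in mutants. All 11 listed IAP families were higher on both strands (median log2 2.81 sense, 2.35 antisense). IAPLTR1_Mm sense reads rose from 247 ± 52.3 to 2779 ± 95.4 RPM (SD, n = 2; log2 4.06 ± 0.15), IAPEz-int sense reads from 2790 ± 1066 to 18221 ± 1532 (log2 3.28, with 2.49 in antisense), and IAPA_MM-int and IAPEY3-int sense reads by log2 4.22 and 3.63. All 3 young L1 families rose on both strands (medians 2.86 and 2.32). L1Md_T went from 5002 ± 1616 to 27278 ± 443 RPM in sense (log2 3.02), L1Md_A from 4379 to 20068 (log2 2.76), and L1Md_Gf by log2 2.86. Older L1 (15 and 14 of 15, medians 1.52 and 1.40), other ERVK (8 and 8 of 9, 2.52 and 2.32), ERV1 (6 and 6 of 6, 1.81 and 1.77) and MERVL (2 and 2 of 2, 1.83 and 1.47) were also higher, with MMERVK10C-int, ETnERV-int, RLTR4_MM-int and MERVL-int sense reads at log2 2.52, 2.66, 2.59 and 2.02. RLTR10-int rose from 736 to 6231 RPM in sense (log2 3.65). MaLR had 5 and 4 of 6 higher (medians 1.01 and 0.52, MTA_Mm sense at 1.63), the antisense median turning to -0.04 with library totals. SINEs went the other way, with 6 of 12 families lower on each strand (medians -0.29 and -0.30), ID_B1 sense at log2 -0.67 (adjusted p = 0.0001), and B1_Mur2 sense at -0.69. The old families L2b antisense, RMER16B3 sense and RNERVK23-int sense fell by 0.73, 1.60 and 2.93 on the log2 scale.

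The counts of each MILI list were equal when adjusted over the list alone. Each of the 16 lists moved by fry (adjusted p between 0.000106 and 0.0438), and none with camera (adjusted p = 0.217 to 0.508 with an estimated correlation). Scaled by library totals the median family stood at log2 -0.59, with 286 higher and 1028 lower, and DESeq2 gave 494 higher and 202 lower.

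Genes in MILI gave 687 calls of 5273, 277 higher and 410 lower. Thbd, the thrombin receptor thrombomodulin (chromosome 2, 148404471 to 148408188), rose from 3.94 ± 1.15 to 20.2 ± 0.663 RPM (SD, n = 2; log2 3.11 ± 0.26, adjusted p = 3.4e-11). Sfi1, a centrosome protein (chromosome 11, 3131850 to 3203347), rose by log2 2.06, Abca1, a cholesterol exporter (chromosome 4, 53030789 to 53159988), by 2.72, Apoh, a plasma lipid-binding protein, by 3.95, and Bhmt2, a methyltransferase of methionine metabolism, by 2.06. Cdv3 (chromosome 9, 103353102 to 103365835) fell from 56.6 ± 3.32 to 2.27 ± 0.270 RPM (log2 -3.87 ± 0.32, adjusted p = 3.4e-11). Hif3a, a subunit of the hypoxia-inducible factors (chromosome 7, 17030993 to 17062427), fell from 42.8 to 4.60 (log2 -2.45), and Cbx5, the heterochromatin protein HP1 alpha (chromosome 15, 103191546 to 103239904), from 483 ± 40.6 to 111 ± 32.9 (log2 -1.40, adjusted p = 4.8e-05). Tmod2, an actin capping protein, Homer2, a synaptic scaffold, Tbl1xr1, a co-repressor subunit, and Zfp524, Ssc4d and Mllt6 fell by 2.30, 1.82, 1.499, 2.21, 1.90 and 1.58 on the log2 scale.

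Of 41 histone genes tested in MILI, 20 were higher, 31 when adjusted over the list alone, and 0 lower (median log2 1.06, fry adjusted p = 0.000548, and 0.0117 with an estimated correlation). Hist1h2ab (chromosome 13, 23751088 to 23751592) stood at log2 1.66, Hist1h2ac at 1.43 and Hist3h2a at 1.14, the last pair without a call by library totals (log2 0.71 and 0.42, adjusted p = 0.08 and 0.32), where the list median was 0.32. Ribosomal protein genes had 8 higher and 1 lower of 32 tested (9 and 1 over the list alone), with Rplp1 at log2 1.41 and Rps20 at 1.11 among the higher (median 0.56, fry adjusted p = 0.0248; adjusted p = 0.201 with an estimated correlation). Their median turned to -0.19 by library totals, where Rplp1 (log2 0.63, adjusted p = 0.14) and Rps20 (0.35, 0.42) were no longer called. piRNA pathway genes had 2 higher, Morc1 (log2 0.95) and the helicase Mov10l1 (0.75), and 1 lower, Exd1 (-0.90), of 9 tested (median 0.02, fry adjusted p = 0.462). Germ cell (4 tested, median 0.31, 0.462) and Leydig genes (2 tested, median -0.21, 0.473) had 0 called, and Sertoli, interstitial, blood and endothelial genes had fewer than 2 members tested in the precipitates.

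Morc1 (adjusted p = 0.045) lost its call without any 1 of the 8 precipitates (adjusted p from 0.06 to 0.39). Exd1 (adjusted p = 0.049) lost it without heterozygous MILI library 1 (0.15) or 2 (0.24) or mutant MILI library 1 (0.33) or 2 (0.066). The Mov10l1 call (adjusted p = 0.036) held only without mutant MILI library 2, and gave 0.28 without heterozygous MILI library 1, 0.064 without heterozygous MILI library 2, 0.16 without mutant MILI library 1, 0.13 without heterozygous MIWI2 library 1 or 2, and 0.081 and 0.094 without mutant MIWI2 libraries 1 and 2. The gene count was 307 without heterozygous MILI library 1, 359 without heterozygous MILI library 2 and 309 without mutant MILI library 1. DESeq2 called 345, and scaling by library totals, where the median gene stood at log2 -0.68, gave 40 higher and 1697 lower. Morc1 and Mov10l1 were then not called (log2 0.22 and 0.01, adjusted p = 0.7 and 0.98).

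Windows of 10 kb gave 27483 calls of 59470 in MILI, 15237 higher and 12246 lower. The window at chromosome 7, 48300001 to 48310000, rose from 0.303 to 19.9 RPM (log2 6.54 ± 0.39, adjusted p = 8.7e-10), and those from 111240001 on chromosome 2 and 87040001 on chromosome 5 by log2 6.24 and 6.19. The window from 103350001 on chromosome 9, over Cdv3 and Topbp1, fell from 55.6 to 2.20 (log2 -4.01), that from 28060001 on chromosome 5 from 62.4 to 3.34, and that from 87620001 on chromosome 6, at Aplf, by 3.93 on the log2 scale. In the most abundant cluster, on chromosome 7, windows from 6600001, 6610001 and 6640001 were called (log2 0.88, 0.99 and 0.66). That from 6620001 was not (adjusted p = 0.067), and none was with library totals. DESeq2 gave 13643 higher and 4391 lower and library totals 12003 and 29683 (median log2 -0.86).

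The third comparison asked the same of MIWI2, the nuclear PIWI protein that directs DNA methylation of elements. In mutants IAP and sense L1 shares were again larger, and SINE, gene and unannotated shares smaller. Elements gave 77.3% ± 1.26 of piRNA-sized reads in heterozygotes and 88.5% ± 0.398 in mutants (SD, n = 2 each; exact p = 0.333 here and for each MIWI2 share below unless given). LTR reads stood at 43.7% ± 0.626 and 58.9% ± 1.30, LINE reads at 23.9% ± 0.122 and 26.3% ± 0.698, and IAP reads at 9.91% ± 0.361 and 18.04% ± 0.123. SINE reads fell from 9.17% ± 0.538 to 2.95% ± 0.214, exon reads from 2.29% ± 0.213 to 0.889% ± 0.103, intron reads from 5.01% ± 0.304 to 2.44% ± 0.130, and reads outside genes and repeats from 13.9% ± 0.316 to 7.50% ± 0.126, by the combined permutation test. Antisense reads made up 67.7% ± 0.647 of IAP reads in heterozygotes and 59.9% ± 0.401 in mutants, and 75.8% ± 1.04 and 69.5% ± 1.62 of L1 reads. Uridine at base 1 stood at 73.9% ± 0.107 and 74.3% ± 0.402 (the difference was -0.596 points with distinct sequences counted once), and adenine at base 10 at 44.9% ± 0.449 and 46.9% ± 0.0631. The 10-nt overlap z-score was 20.6 ± 0.692 and 19.9 ± 3.33, a difference from -3.13 without mutant library 2 to 1.58 without mutant library 1. piRNA-sized reads made up 93.4% ± 0.139 and 93.0% ± 0.171 of all MIWI2 reads.

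Of 1852 family features, 803 were called in MIWI2, 415 higher and 388 lower. All 11 IAP families were higher in sense and 10 in antisense (medians 1.28 and 0.90), with IAPEz-int from 11607 to 31943 RPM in sense (log2 2.37) and from 21360 to 45468 antisense (log2 1.999). IAPLTR4_I sense reads rose from 169 to 783 RPM (log2 3.13 ± 0.13, adjusted p = 3.7e-15; antisense log2 2.99), and IAPEY3-int sense reads from 1939 to 7297 (log2 2.82). All 3 young L1 families were higher on both strands (medians 1.81 and 1.24). L1Md_T sense reads rose from 15296 to 32552 RPM (log2 1.999) and its antisense reads by log2 1.24, while L1Md_A, at log2 0.96 sense and 0.87 antisense, went from 8433 to 8755 and from 15043 to 14669 RPM, its antisense change turning to -0.04 with library totals. Older L1 (13 and 13 of 15, and 13 and 14 over the list alone, medians 0.76 and 0.71) and MERVL (2 and 2 of 2, medians 1.03 and 0.90) had no member lower, but by library totals the older L1 lists on both strands and antisense MERVL turned lower. The old families L1MB8 and LTR84b rose as well, L1MB8 by log2 2.57 in sense and 2.36 in antisense and LTR84b antisense by 3.67. Other ERVK had 8 sense families higher and 1 lower and 7 and 1 in antisense (medians 1.72 and 1.30), with RLTR10-int sense at log2 2.73, and ERV1 had 5 and 4 of 6 higher (5 and 4 higher and 1 and 1 lower over the list alone, medians 0.96 and 1.29), sense ERV1 turning lower by library totals. MaLR was split, with 2 higher and 2 lower in sense (median -0.01, mean 0.02, fry adjusted p = 0.971, downwards with camera) and 1 and 3 in antisense (1 and 4 over the list alone, median -0.32, 0.0942), where ORR1A2 stood at log2 -0.66.

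SINEs fell in MIWI2 on both strands, 10 of 12 families each (medians -0.74 and -0.82, both fry adjusted p = 0.00218; both 0.329 with an estimated correlation). B1_Mus2 antisense went from 6012 ± 936 to 1244 ± 158 RPM (SD, n = 2; log2 -1.37), B1_Mus1 antisense from 7589 ± 1111 to 1720 ± 172 (log2 -1.24), and B2_Mm2 antisense fell by 0.89 on the log2 scale. RMER10A sense reads fell from 211 to 38.6 RPM (log2 -1.54) and MURVY-LTR sense reads from 766 to 175 (log2 -1.22). The MIWI2 lists that passed fry did so at adjusted p between 0.000731 and 0.00678, and none passed with camera (adjusted p = 0.329 to 0.344 with an estimated correlation). Where no other count is given, list counts were equal when adjusted over the list alone. Scaled by library totals the median family stood at log2 -1.02, with 113 higher and 1146 lower. L1Md_T antisense (log2 0.33, adjusted p = 0.075) and L1Md_A sense (log2 0.05, 0.78) were then not called.

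Genes in MIWI2 gave 257 calls of 5273, 51 higher and 206 lower. Thbd rose here too (log2 2.88 ± 0.43, adjusted p = 1.3e-05), with the cadherin Cdh3 (chromosome 8, 106510852 to 106556911) at log2 2.42 ± 0.39. Without heterozygous MIWI2 library 1 and 2 Cdh3 stood at 1.35 and 3.41. Cdv3 fell from 60.6 ± 6.26 to 1.06 ± 0.673 RPM (SD, n = 2; log2 -4.79 ± 0.38, adjusted p = 8.1e-12), Aplf, a DNA end-joining factor (chromosome 6, 87628425 to 87672237), by 4.35 on the log2 scale, and Jund, an AP-1 transcription factor (chromosome 8, 70697739 to 70700616), from 37.7 to 3.92 (log2 -2.27). Neat1, the noncoding RNA of paraspeckles (chromosome 19, 5824708 to 5845480), fell from 113 to 15.0 RPM (log2 -1.93), Cbx5 from 66.1 to 9.92 (log2 -1.76), and Rn45s, Ssc4d, Bcam and Orai3 by 2.13, 2.51, 1.95 and 1.82. Ftl1, the ferritin light chain (chromosome 7, 45457944 to 45459886), fell from 21.1 ± 0.166 to 1.27 ± 0.136 (log2 -3.04), but by log2 -0.60 with distinct sequences counted once (adjusted p = 0.58). Ribosomal proteins had 1 higher, Rplp1 (log2 1.40), and 1 lower, Rps2 (-1.70), of 32 tested, with 2 and 1 when adjusted over the list alone (median 0.84, fry adjusted p = 0.31). piRNA pathway (median 0.23, 0.53), germ cell (0.85, 0.53), Leydig (-0.43, 0.642) and histone genes (0.77, 0.23) had 0 called, also when adjusted over the list alone, and all but Leydig turned lower with library totals.

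Rplp1 lost its call without any one of the MIWI2 libraries (adjusted p = 0.15 and 0.3 without heterozygous 1 and 2, 0.28 and 0.1 without mutant 1 and 2) and with library totals (log2 0.38, adjusted p = 0.53). The gene count was 124 without mutant MIWI2 library 1, 63 higher and 139 lower with DESeq2, and 123 and 107 when MIWI2 was fitted alone. By library totals it was 12 and 1217, with the median gene at log2 -1.10.

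Windows of 10 kb gave 20297 calls of 59470 in MIWI2, 12342 higher and 7955 lower. With library totals these were 7195 and 26442, and the median window stood at log2 -1.26. DESeq2 gave 11438 and 3533. The window at chromosome 7, 90860001 to 90870000, in the synaptic gene Dlg2, rose from 1.60 to 76.3 RPM (log2 6.55, adjusted p = 1.3e-09), and those from 27130001 and 45760001 on chromosome 11 by log2 5.09 and 5.02. The window from 97270001 on chromosome 9 fell from 432 to 12.4 (log2 -4.10, adjusted p = 1.9e-09), that from 8990001 on chromosome 8 from 303 to 9.90 (log2 -3.93), and that from 100750001 on chromosome 14 from 279 to 14.6 (log2 -3.26).

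**Figure D4:**
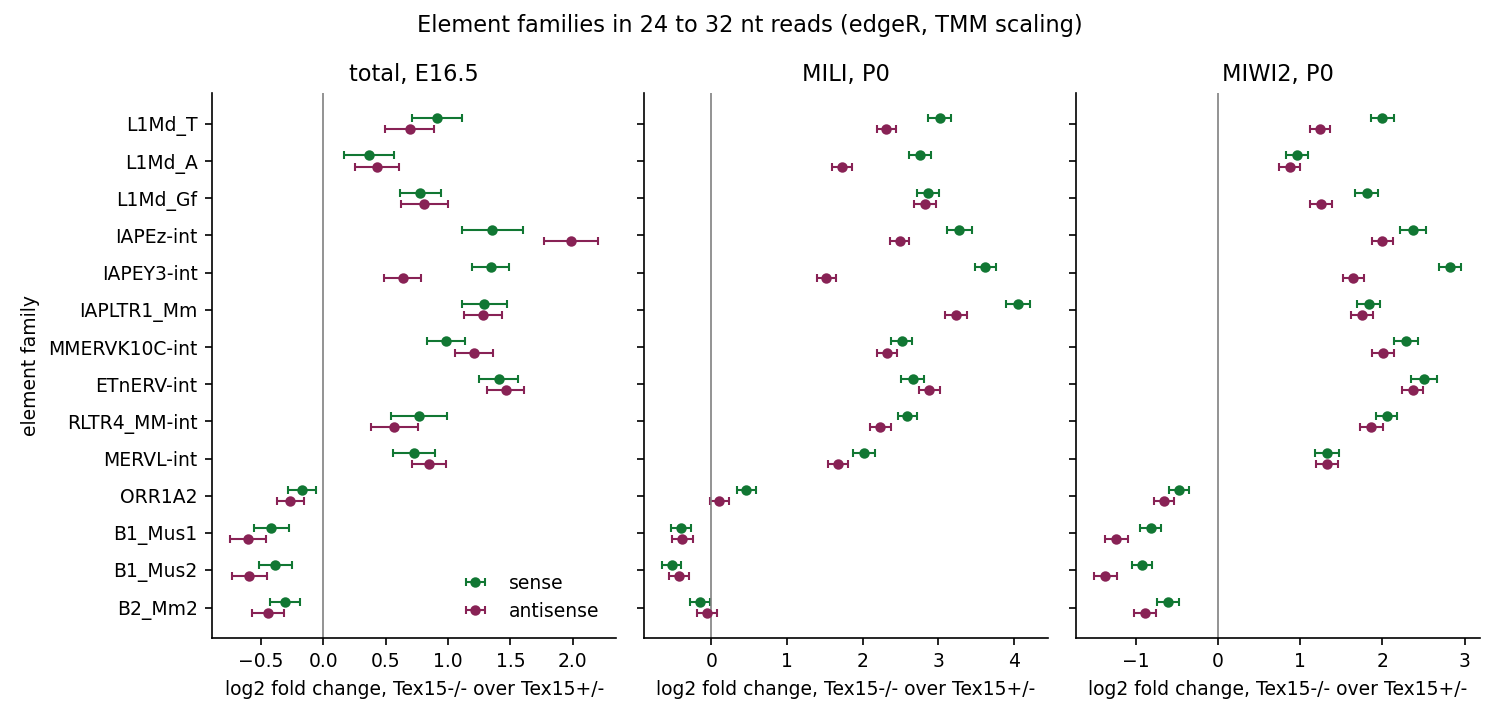
Log2 difference of mutant over heterozygote with its standard error for 14 element families, sense and antisense, in total small RNA, MILI and MIWI2 (edgeR, TMM scaling). IAPEz-int sense stands at 1.36, 3.28 and 2.37 and L1Md_T sense at 0.91, 3.02 and 1.999, the first value of the latter turning to -0.08 when total RNA is scaled to microRNA reads, and B1_Mus1 antisense lies below 0 in all 3.

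Whether the effect of the mutation differed between the antibodies was tested as the interaction, MIWI2 effect minus MILI effect. Of 1852 family features, 413 differed, 68 with a higher and 345 with a lower effect in MIWI2, and 16 and 629 with library totals. IAPLTR2a2_Mm antisense reads went from 304 to 1353 RPM in MILI and from 1826 to 1119 in MIWI2 (interaction log2 -2.52, adjusted p = 4.2e-09). IAPLTR1_Mm and IAPLTR1a_Mm sense stood at -2.22 and -2.18, L1Md_A sense at -1.80, and L1Md_Gf antisense at -1.57, while L1MB8 sense and antisense (1.47 and 1.34) and MLT1E1A sense (1.76) went the other way. All 16 element lists moved downwards by fry (adjusted p between 0.00606 and 0.0485; adjusted p = 0.353 to 0.742 with an estimated correlation). IAP had 10 of 11 lower and 1 higher in sense and 8 lower in antisense (medians -1.44 and -0.78), young L1 3 and 3 of 3 (-1.05 and -1.08), older L1 12 and 12 of 15 (-0.77 and -0.69), other ERVK 6 and 7 of 9 (-0.69 and -1.11), ERV1 6 and 3 of 6 (-0.95 and -0.63), MERVL 2 and 1 of 2 (-0.80 and -0.56), MaLR 5 and 5 of 6 (-0.97 and -0.93), and SINEs 3 and 6 of 12 (-0.30 and -0.56). Adjusted over the list alone, older L1 had 13 and 13 lower, antisense IAP 9, antisense ERV1 4, antisense MaLR 6 and antisense SINEs 7, with the other counts equal.

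Genes gave 4 interaction calls of 5273, 0 higher and 4 lower. In simulated data this comparison called 3 unchanged genes by mistake. The 4 called here were Ftl1 (log2 -2.80 ± 0.48, adjusted p = 0.0051; -0.46 with distinct sequences, adjusted p = 0.94), H13, the signal peptide peptidase (chromosome 2, 152669422 to 152708668; log2 -2.45, adjusted p = 0.041), Jund (-1.74, 0.049) and 4930539E08Rik (-1.92, 0.049), the last a predicted gene named after its values were seen. H13 lost its call without mutant MIWI2 library 1 (adjusted p = 0.057) or 2 (0.094), and Jund without heterozygous MILI library 1 (0.067) or mutant MIWI2 library 1 (0.09) or 2 (0.052). 4930539E08Rik lost it without mutant MILI library 1 (0.077) or mutant MIWI2 library 2 (0.09). The count was 8, 11, 7 and 13 without heterozygous MILI library 1 and 2 and mutant MILI library 1 and 2, and 12 and 2 without heterozygous MIWI2 library 2 and mutant MIWI2 library 1. Of the 4, only Ftl1 kept its call with library totals. No gene list moved (fry adjusted p between 0.664 and 0.894).

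Windows gave 23 interaction calls of 59470, 10 higher and 13 lower in MIWI2, and 13 and 342 with library totals. The higher ones included microRNA loci, the window at chromosome X, 53050001 to 53060000, with Mir351, Mir503 and Mir322, which went from 3.88 to 47.4 RPM in MIWI2 and from 3.51 to 3.55 in MILI (log2 4.01, adjusted p = 0.0057), and that from 30160001 on chromosome 6 with Mir182, Mir96 and Mir183 (log2 3.50). microRNA precursor reads as a whole numbered 2891 and 3053 in heterozygous and 11044 and 14415 in mutant MIWI2 libraries, against 2644 and 3923 and 1638 and 1708 with MILI. Smaller rises in MIWI2 lay at 81540001 on chromosome 11, in Asic2 (log2 -3.14), and 11780001 on chromosome 1 (log2 -3.26). The window on chromosome 6 lost its call without heterozygous MIWI2 library 1 (log2 3.05, adjusted p = 0.068), that on chromosome 11 without heterozygous MILI library 2 (0.053), and that on chromosome 1 without heterozygous MILI library 1 (0.063) or 2 (0.055). The count moved from 23 to 8, 14, 36 and 109 without heterozygous MILI library 1 and 2 and mutant MILI library 1 and 2, and to 14, 139 and 60 without heterozygous MIWI2 library 2 and mutant MIWI2 library 1 and 2.

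The last comparison asked how the piRNAs of MIWI2 and MILI differed where Tex15 was present, with log2 values of MIWI2 over MILI. MIWI2 held longer RNAs with more antisense L1 and more adenine at base 10, and a smaller share of exon reads (2.29% against 10.7%; exact p = 0.333). In heterozygotes MIWI2 reads were 1.12 nt longer, had 10.7 points less uridine at base 1 (difference -10.7), 16.9 points more adenine at base 10 and 20.6 points more antisense among L1 reads, and differed by -3.60 points in the antisense share of IAP reads (n = 2 each; exact p = 0.333 each). The L1 difference was 27.5 points without the exact chromosome 9 sequence, whose other forms stayed in, and 31.4 and 9.88 without heterozygous MILI library 1 and 2. In mutants these differences were 0.998 nt and -8.22, 16.0, 36.6 and 8.98 points. With distinct sequences counted once, the adenine and IAP differences were 9.91 and -0.132 points in heterozygotes and 10.4 and 2.23 in mutants. Families gave 1188 calls of 1852 in heterozygotes, 576 higher and 612 lower with MIWI2, and 890 in mutants, 474 higher and 416 lower. Antisense L1Md_Gf, L1Md_A and L1Md_T stood at log2 5.11, 4.64 and 4.56, against 2.37 for sense L1Md_T, and antisense and sense IAPEz-int at 4.66 and 2.82. Antisense MERVL-int (4.31) and B1_Mus2 (1.87) were higher as well, and MMTV-int (-1.71) and RLTR34C_MM (-1.33) antisense were lower, though neither with distinct sequences counted once (-0.27 and -0.17, adjusted p = 0.15 and 0.18).

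Each listed family of young L1 (3 and 3, sense and antisense, medians 2.17 and 4.64), IAP (11 and 11, 2.39 and 2.93), other ERVK (9 and 9, 2.48 and 2.85), ERV1 (6 and 6, 2.03 and 3.10), MERVL (2 and 2, 2.64 and 3.86) and MaLR (6 and 6, 1.57 and 2.20) was higher with MIWI2 in heterozygotes. Older L1 had 12 higher and 2 lower in sense (median 0.89, turning lower with library totals) and 13 higher in antisense (3.03), and SINEs 4 higher and 2 lower in sense (median -0.02, mean 0.10, fry adjusted p = 0.268, downwards with camera) and 9 higher in antisense (1.16). These counts were equal when adjusted over the list alone. In mutants the medians were 1.11 and 3.54 for young L1, 1.27 and 1.61 for IAP, 1.33 and 1.92 for other ERVK, 1.28 and 2.51 for ERV1, 1.85 and 3.30 for MERVL, 0.57 and 1.18 for MaLR, -0.04 and 2.31 for older L1, and -0.25 and 0.76 for SINEs. Older L1 then had 2 higher and 5 lower in sense (fry adjusted p = 0.813), SINEs 1 and 4 (0.0589), and sense MaLR 5 higher, or 6 when adjusted over the list alone. Sense young L1 and MaLR and antisense SINEs turned lower there with library totals. With an estimated correlation the lists gave adjusted p = 0.156 to 0.871 in heterozygotes and 0.129 to 0.832 in mutants.

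Genes gave 908 calls of 5273 between MIWI2 and MILI in heterozygotes, 537 higher and 371 lower, and 251 in mutants, 150 higher and 101 lower. Sfi1, Zdhhc14 (chromosome 17, 5492562 to 5753891) and Kcnk12 (chromosome 17, 87745821 to 87797994) were higher with MIWI2 by log2 4.29, 4.22 and 3.71. Ftl1 stood at 4.28 (adjusted p = 3.8e-16). With library totals these stood at 1.52, 1.46, 0.93 and 1.47. Nanos2 (chromosome 7, 18987524 to 18988962) stood at log2 2.74 but at -0.07 with library totals. Rpl30 (chromosome 15, 34440505 to 34443276) was lower with MIWI2 by log2 -2.87, Atp5e by -2.96, Psmb1 by -2.47 and Sod1 (chromosome 16, 90220762 to 90226333) by -1.60. With distinct sequences counted once Rpl30 and Sod1 turned to 0.43 and 0.22 and the other two were not called (log2 -1.08 and -0.52; adjusted p = 0.12 and 0.33). Mael, a piRNA pathway protein (chromosome 1, 166201385 to 166238744), and Gtsf1 were lower by log2 -2.23 and -3.69, the 2 called of 9 pathway genes (median -0.23, fry adjusted p = 0.0693). Germ cell genes had Nanos2 higher and Dazl lower (log2 -2.62; median 0.49, 0.109), turning lower on balance with library totals. Without heterozygous MIWI2 library 2 Gtsf1 (log2 -2.90, adjusted p = 0.11) and Dazl (-1.80, 0.31) were not called, and Mael stood at -1.62. Without library 1 Gtsf1, Dazl and Mael stood at -7.71, -7.59 and -3.77. Histones had 3 higher and 9 lower (4 and 11 over the list alone, median -0.75, 0.073) and ribosomal proteins 1 and 9 (2 and 10 over the list alone, median -0.59, 0.0693), and Leydig genes 0 called (median -0.19, 0.692).

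In mutants histones had 0 higher and 8 lower (0 and 12 over the list alone, median -0.91, fry adjusted p = 0.0465; adjusted p = 0.174 with an estimated correlation) and ribosomal proteins 0 and 5 (1 and 12 over the list alone, median -0.53, 0.0881). piRNA pathway genes had 0 called and 1 lower over the list alone (median -0.63, 0.127), germ cell genes 1 higher (median 0.41, 0.115, lower on balance with library totals) and Leydig genes 0 (median -0.41, 0.671). With library totals the median gene stood at log2 -2.90 in heterozygotes and -3.26 in mutants, with 20 higher and 5054 lower and with 9 and 5042. The median family stood at -0.95 and -1.30, with 348 and 1232 families and with 146 and 1372. DESeq2 gave 562 and 316 families in heterozygotes and 499 and 208 in mutants, and 194 and 57 genes in mutants. The gene count in heterozygotes was 377 and 409 without heterozygous MIWI2 library 1 and 2 and 584 without heterozygous MILI library 1, and in mutants 97 and 99 without mutant MIWI2 library 1 and 2.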

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

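Among the tests of explanations below, the match of 3 microRNA names to the ribosomal RNA locus and the make-up of a chromosome 9 window were fixed before their results were seen, and the other tests of explanations, the splits of the total libraries included, were chosen only after the result was seen.

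By the interaction test on log2 ratios, the mutation's effect differed between antibodies for 4 genes, 413 element family features and 23 windows. By fry, but not with an estimated correlation, 16 element lists differed. Elements held more of heterozygous MIWI2 than MILI reads, so a lower log2 effect there need not mean fewer points gained. The share with uridine at base 1 moved by -2.08 points with MILI and 0.401 with MIWI2 in every library. These lay 2.48 points apart, untested. With distinct sequences counted once the MIWI2 difference was -0.596 points, so the opposite directions rest on counting each read. The antisense share of IAP reads was lower with MIWI2 than with MILI in heterozygotes (-3.60 points) and higher in mutants (8.98 points), 12.6 points apart, which was not tested either.

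mir-6236, mir-6240 and mir-6538 were higher in mutant total libraries, where ribosomal RNA reads also took a larger share. Of the reads of mir-6236 66.6% (18070 of 27139) and of mir-6240 98.8% (5633 of 5700) share a stretch of 16 nt with reads annotated as ribosomal RNA, against 0 of 10212483 reads of the 10 most abundant microRNAs, so ribosomal RNA fragments counted as microRNA are a candidate explanation for these names. For mir-6538 it was 0 of 488 reads, which leaves the question open, since the ribosomal RNA reads were not shown to cover the whole molecule. An exact match to the annotated ribosomal RNA locus had been set beforehand to speak against this explanation if it was rare, and it was 0% for the 3 names, but it was also 0% for the reads annotated as ribosomal RNA, so that this bound was wrong and decides nothing. More degraded RNA in the mutant libraries cannot be told apart from a difference between genotypes, since transfer RNA reads, which it would raise as well, differed by -2.23 points, less than the summed SDs, and a biological difference stays open, untested.

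Element reads took a larger share of piRNA-sized reads in each mutant precipitate. With distinct sequences counted once the share still differed by 15.7 points with MILI and 11.5 with MIWI2 (summed SDs 5.19 and 1.61). Among uniquely placed reads it differed by 10.5 and 11.7 (3.13 and 1.49). Neither a few abundant sequences nor reads shared between copies account for all of it. How large a part they give was not tested. Whether element piRNAs rose or other piRNAs fell stays open, as the precipitates have no outside standard. Per 100 microRNA reads in total RNA, IAP, L1 and LTR reads differed by 3.52, -7.97 and -3.07, within the spread. SINE, unannotated, intron and exon reads differed by -4.38, -7.24, -3.42 and -2.53, with only SINE groups apart (exact p = 0.1). A larger supply of element transcripts in the mutant was not tested, since these libraries do not measure them.

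A single 28 nt sequence, TGACATGAACACAGGTGCTCAGATAGCT, at chromosome 9, 67709554 to 67709581 on the minus strand and antisense to an L1M2 element, gave 245782 reads in heterozygous MILI library 1 (2.85%, Wilson 95% interval 2.84 to 2.86) and 62 in heterozygous MILI library 2. It gave 18932 reads (0.251%) in heterozygous MIWI2 library 1 and 4031 in mutant total library 1. Other reads within 200 kb were 1.055 times as frequent in heterozygous MILI library 1 as in its replicate (71.5 and 67.8 RPM), which argues against a rise of the whole locus. Of the reads of its 10 kb window in that library 99.98% were this sequence or shorter or longer forms of it, among them 16422 reads of a form of 30 nt. The sequence alone gave 86.3% of them, which largely fixes this share, so it does not tell a molecule copied or added during library preparation from a single abundant piRNA, and the cause stays open.

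The 6 total libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 3 microRNAs, 116 family features and 1503 windows, the highest other split 0, 0 and 1, and 1 of 10 splits gave as many in each case. For genes the real split gave 0 and the highest other 2, and 10 of 10 splits gave at least as many.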

How the results depend on the processing

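Among the alternatives below, microRNA names as in the file, leaving out the chromosome 9 sequence, reads with any number of alignments, uniquely placed reads for the element and IAP shares, and library totals for the lists were chosen after the results were seen, and the other tests were fixed before.

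The labels do not say whether the libraries of a group came from separate animals, and in every way of counting each sequence was placed at the alignment listed. Weighting each alignment by 1 over its number was not run. No paired analysis was made because the labels give no replicate numbers, and numbers in the order of listing only name the libraries. In that order, the differences between library 1 and 2 with MILI and with MIWI2 were correlated in both genotypes (r = 0.357 to 0.616 over families, genes and windows). The fit of 4 groups takes these libraries as independent, so its interaction and MIWI2 against MILI results are untested against pairing. With 2 libraries per group in the precipitates, leaving 1 out leaves a lone sample, which is assumed to vary like the other groups. Depth, 5106928 to 11972688 reads, limits the genes and windows that passed the filter. The cause of a changed result was not tested anywhere below.

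Over single features, 2545 alternatives were run on 163 results. Of these, 2389 gave the same result, 138 a weaker one and 9 a stronger one, and 9 changed direction. For lists, 270 alternatives gave 112 the same, 108 weaker, 10 stronger and 40 reversed. For shares and z-scores, 544 gave 523 in the same direction and 21 reversed. For counts of calls, 263 gave 196 within 1.5 times the usual count and 67 beyond it. Camera weakened 89 of 135 list results and reversed 3. These were Leydig genes in the interaction (adjusted p = 0.965), sense MaLR in MIWI2 (0.924) and sense SINEs in MIWI2 against MILI in heterozygotes (0.871). microRNA names as in the file, leaving out the chromosome 9 sequence and fitting each antibody alone moved no summed count beyond 1.5 times and turned no direction of a feature or share. Fitted alone, however, MIWI2 gave 123 genes higher and 107 lower, against 51 and 206 in the joint fit.

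Scaling by library totals moved 14 of 17 counts of calls. Gene calls became 360 in total RNA, 1737 in MILI, 1229 in MIWI2, 1 in the interaction, and 5074 and 5051 for MIWI2 against MILI in heterozygotes and mutants. Family calls became 1 in total RNA, 1259 in MIWI2, 645 in the interaction and 1518 for MIWI2 against MILI in mutants. Window calls became 2714, 41686 and 33637 in total RNA, MILI and MIWI2 and 355 in the interaction. Nanos2 in MIWI2 against MILI in heterozygotes turned to log2 -0.0691 and antisense L1Md_A in MIWI2 to -0.0363.

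Of the lists, 37 changed the direction of the fry test with library totals, given here with their fry adjusted p. This direction can differ from the sign of the list median, as for both IAP lists in total RNA and antisense MaLR in MILI, where only the median turned. In total RNA these were somatic gonad microRNAs and Mir34b with Mir449 (both 0.898), and piRNA pathway (0.406), histone (0.339) and ribosomal protein genes (0.339). Also in total RNA, young L1, other ERVK and MERVL on both strands and sense older L1 stood at 0.878, antisense older L1 at 0.620 and ERV1 on both strands at 0.488. In MILI the genes were piRNA pathway (0.0166), germ cell (0.398) and ribosomal protein (0.360). In MIWI2 they were piRNA pathway (0.161), germ cell (0.597), histone (0.597) and ribosomal protein (0.389), and in the interaction piRNA pathway (0.939), germ cell (0.990) and ribosomal protein (0.939). The MIWI2 element lists were older L1 in sense (0.515) and antisense (0.191), sense ERV1 (0.808), antisense MERVL (0.808) and sense MaLR (0.0203). For MIWI2 against MILI in heterozygotes they were germ cell genes (0.0163), sense older L1 (0.522) and sense SINEs (0.00133). In mutants they were germ cell genes (0.0226), sense young L1 (0.242), sense MaLR (0.0642) and antisense SINEs (0.0338).

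DESeq2 called 1 gene in total RNA, 345 in MILI and 2 in the interaction, and 18034 windows in MILI and 72 in the interaction. RLE size factors left 1 interaction gene. Without the filter on low counts 14 genes were called in total RNA, 14 genes in the interaction and 377 windows in the interaction. Scaling total RNA to microRNA precursor reads gave 16 genes and 0 families, and turned sense L1Md_T to log2 -0.0849 and antisense MERVL-int to -0.20. By edgeR 260 families had an unadjusted p under 0.05 there, and DESeq2 called 158 with its own size factors.

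With distinct sequences counted once each, 2 genes were called in total RNA and 0 genes and 3 windows in the interaction. By edgeR 374 genes had an unadjusted p under 0.05 in that interaction, and DESeq2 called 2 by the usual counting. Rpl30 and Sod1 in MIWI2 against MILI in heterozygotes turned to log2 0.43 and 0.22, and the interaction of the window from 70440001 on chromosome 14 to -0.83. In total RNA the LINE share then differed by 4.17 points, antisense L1 reads among piRNA-sized reads by 2.45 and the transfer RNA share by 0.0653. The MILI ping-pong z-score differed by -0.589 and uridine at base 1 in MIWI2 by -0.596 points. Uniquely placed reads reversed the share of all elements (-1.23 points), of LINEs (1.16) and of transfer RNA (0.0289) in total RNA, and antisense L1MDa in MIWI2 against MILI in mutants (log2 -0.11).

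Reads of 26 to 30 nt gave 2 genes and 11 windows in the interaction and turned the chromosome 14 window to -0.39. Reads with any number of alignments gave 3777, 49961, 34896 and 4870 windows in total RNA, MILI, MIWI2 and the interaction. Windows of 50 kb gave 16373 calls in MILI and 152 in the interaction.

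Leaving out 1 library at a time gave, at lowest and highest, 1 and 9 microRNAs, 0 and 112 genes, 63 and 157 families and 970 and 1869 windows in total RNA. Gene calls ran from 307 to 758 in MILI, 124 to 338 in MIWI2, 2 to 13 in the interaction, 377 to 939 for MIWI2 against MILI in heterozygotes and 97 to 342 in mutants. Interaction windows ran from 8 to 139. In total RNA the antisense share of IAP reads differed by -0.174 to 2.83 points, antisense L1 reads among piRNA-sized reads by -1.89 to 0.278, the LINE share by -1.66 to 1.498, and microRNA among all reads by -2.74 to 6.02. The share of antisense L1 reads ran from -0.724 to 2.43 points in MILI and from -0.374 to 0.908 in MIWI2. The ping-pong z-score ran from -0.240 to 0.478 in MILI and from -3.13 to 1.58 in MIWI2. The other results kept their direction.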

Other observations

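All tests below, the shares by element and strand, base 10 by element, the combined permutation and the counts of windows near Tex15, were chosen after the result was seen or the data had been examined.

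L1 and IAP reads were also taken by strand as parts of piRNA-sized reads. With MILI, antisense L1 reads held 5.53% ± 2.23 in heterozygotes and 6.39% ± 0.537 in mutants (SD, n = 2; exact p = 1), the first raised in library 1 by the chromosome 9 sequence. Without it they held 4.11% and 3.95% in heterozygotes and 6.77% and 6.002% in mutants, higher in each mutant library by 2.35 points on average (exact p = 0.333). With MIWI2 they held 17.9% ± 0.144 and 18.2% ± 0.907 (exact p = 1), and in total RNA 15.9% ± 1.66 and 15.2% ± 2.19 (n = 3; exact p = 0.7), a difference that turned to 2.45 points with distinct sequences counted once. These designs cannot show that shares are equal. Sense L1 reads held 5.72% ± 0.278 and 7.98% ± 0.213 with MIWI2 (exact p = 0.333) and 11.2% ± 1.08 and 11.97% ± 0.828 in total RNA (exact p = 0.4). Antisense IAP reads took a larger part in every mutant library, 5.80% ± 0.534 and 9.48% ± 0.520 in total RNA (exact p = 0.1), 2.53% ± 0.376 and 5.34% ± 0.501 with MILI, and 6.71% ± 0.309 and 10.8% ± 0.146 with MIWI2 (exact p = 0.333 each).

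Adenine at base 10 of antisense IAP reads was more frequent in the mutant precipitates, 27.3% ± 1.86 and 32.4% ± 0.0993 with MILI and 48.4% ± 0.586 and 52.3% ± 0.307 with MIWI2 (SD, n = 2; exact p = 0.333 each). For antisense SINE reads it was less frequent in every mutant library, 36.1% ± 0.564 and 34.3% ± 0.362 in total RNA (n = 3; exact p = 0.1), 32.2% ± 1.002 and 30.3% ± 0.398 with MILI and 45.9% ± 0.590 and 43.4% ± 0.642 with MIWI2. Reads from DNA transposons, which do not move through RNA, fell with those of SINEs, from 0.392% to 0.238% of piRNA-sized reads in total RNA, 0.928% to 0.563% with MILI and 0.611% to 0.352% with MIWI2 (combined exact p = 0.0167, adjusted 0.0333, with either antibody).

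Within 15 Mb of Tex15, 46.8% of 602 windows were called with MILI and 33.7% with MIWI2, against 46.2% and 34.1% elsewhere. Windows of total RNA were not counted in this way.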
